A study of Mus musculus with 6 samples.

How the data were processed

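RNA-seq was performed on 6 libraries of mouse KMT2A-MLLT3 leukemia cells, 1 for each of the labels NT, DOT1L Low and DOT1L High in each of 2 leukemias, K3117 and K3174. Per the labels' protocols, RNA was extracted with an RNeasy kit 3 days after the sort and read in pairs of 150 bp on an Illumina HiSeq. The authors deposited a table of whole-number counts per gene with 1 column per library, which was used as deposited. STAR, STAR-Fusion, kallisto, DESeq2 and the build mm10 are named per the submitters' processing notes, without versions or roles, so which of the tools made the counts, the gene annotation and the use of strand are not given in the sources used here. Antisense and overlapping genes therefore cannot be told apart, and counts of close paralogs (the Stfa, Xlr4, Ear, globin and Oas families) are uncertain. Because the reads of a transgene or fusion may or may not align to a mouse gene, counts of Dot1l, Kmt2a and Mllt3 need not follow the introduced constructs.

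The table held 49585 gene IDs, of which 23286 had no count in any library. Symbols came from a GENCODE gene name table, which matched 99.5% of IDs without their version number, and the 259 unmatched IDs held at most 0.0204% of a library's counts. Positions are from the GENCODE annotation of GRCm38, the assembly that mm10 denotes, counted from 1. Total counts per library were between 22908445 and 33265848. The 10 most counted genes took between 3.61% and 4.03% of a library, and mitochondrially encoded genes between 0.979% and 1.44%. No pair of libraries agreed within sampling noise (chi-square per degree of freedom of at least 25.4), so all 6 were kept. Intervals and floors cover counting error or the fitted spread only. A gene without counts in a group was given a floor of 3 counts per library.

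Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by edgeR's expression filter (15812 genes), libraries were scaled by TMM factors between 0.973 and 1.04, and a quasi-likelihood model with the 3 labels and the leukemia as a block was fitted to all 6 libraries, with 2 residual degrees of freedom, 9.38 prior degrees of freedom and a common biological coefficient of variation of 12.0%. Contrasts were High against NT, Low against NT, High against Low, the mean of Low and High against NT, and K3174 against K3117. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over the genes tested. The SE is the fold change divided by the root of its F statistic. CPM values use the TMM library sizes, and log2 CPM differences within a leukemia use a prior count of 2.

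The block was part of the design because the library titles give each K number to 1 library of every label and the protocol sorts the populations from transduced marrow. That a K number marks 1 leukemia is read from the titles and not stated. The deviations of the 2 leukemias from their group means correlated across genes at 0.57 between NT and Low, 0.44 between NT and High and 0.64 between Low and High. Counts without the block stand beside the main count of each contrast of the labels. Whether the 2 K numbers are separate mice is also not stated, and if they are not, the p-values measure only the spread between these samples.

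Before the data were examined, 29 gene lists with 612 members were fixed, of which 611 were in the table. They covered KMT2A fusion targets, DOT1L partners and elongation factors, stem and progenitor genes, primary granule, late neutrophil, monocyte, dendritic cell, mast cell, erythroid, megakaryocyte, T and NK cell, B cell and stromal genes, S phase, G2 and M phase, p53 targets, Cdkn inhibitors and apoptosis, interferon, inflammatory NF-kB, immediate early, MYC and ribosome biogenesis, ribosomal proteins, unfolded protein and integrated stress responses, heat shock, hypoxia and glycolysis, cholesterol synthesis, mitochondrially encoded, histone and long neuronal or muscle genes. None was chosen on these samples, though the granulocyte, monocyte and mast cell lists hold genes that leukemia cells of this kind can express, and Flt3 is on 2 lists. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01 and again with an estimated correlation, under which no list passed in any contrast. With fry, which asks whether a list's genes move 1 way on balance and makes no comparison with other genes, 10, 0, 6 and 5 lists passed for High against NT, Low against NT, High against Low and the mean against NT. The p-values of camera are adjusted over the 29 lists of a contrast.

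Named genes followed a rule fixed at the same time. It took Dot1l in every contrast, the 10 rising and 10 falling genes with the largest fold change for High against NT (6 and 6 for the other contrasts) among named genes past the threshold with the same direction in both leukemias and a mean CPM of at least 5 in the higher group, the 4 members with the smallest p of each list that passed camera, and Hoxa9, Meis1, Pbx3 and Mef2c with further called fusion targets. List members named beyond it, such as Mmp8, Myb, Cpeb2, Cdca7, Perp, Fas, Cd34, Kit, Aff1, Mllt3, Mllt6, Prss34 and Ctss, were chosen after their values were seen.

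The procedure was tested on simulated counts of 15512 genes with the libraries' means and dispersions and 200 changed genes. For High against NT it recovered 87% of 100 genes changed by 1 and 100% of 100 genes changed by 2 on the log2 scale, with 8 false among 195 calls. For Low against NT, it recovered 25% at 0.5 and 89% at 1, with 10 false among 124 calls, and for High against Low 25% at 0.5 and 81% at 1, with 4 false among 110 calls. A planted list had a camera p of 2.3e-79 with the preset and 0.0022 with the estimated correlation. Of the unchanged lists, 0.5% had a p below 0.05 with the preset and 0% with the estimated correlation. The simulated genes were drawn independently of each other, so this could not show how either setting performs on lists whose members vary together. The changed genes were drawn from those with an average log2 CPM above 1.

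Alternatives were RLE, upper quartile and library-size scaling, no filter or a CPM of at least 5 in at least 2 libraries, DESeq2 1.42.0, limma-voom, robust dispersion, no replicate block, only the compared groups, each library left out, other thresholds and other prior counts. Where a library was left out, the lone library of its group was assumed to vary like the other groups. A test of whether the steps from NT to Low and from Low to High differ (High minus 2 times Low plus NT) was added after the data were examined. Figures were drawn with matplotlib 3.10.9.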

Results

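Gene expression was measured by RNA-seq in mouse acute myeloid leukemia cells driven by KMT2A-MLLT3, a fusion of the histone methyltransferase KMT2A with MLLT3. MLLT3 is a partner of DOT1L, a histone methyltransferase on which leukemias of this kind are known to depend. Marrow of diseased mice was transduced with DOT1L, and cells with low and with high expression were sorted. RNA was collected 3 days after the sort from cells cultured with interleukin 3, interleukin 6 and stem cell factor. The 6 libraries formed 3 groups of 2, named NT, DOT1L Low and DOT1L High by their labels. The labels do not expand NT, which served as the reference group, and whether its cells were transduced or sorted was not established. Contrasts with NT can therefore hold differences of handling as well as of DOT1L. Each group held 1 library of each of 2 leukemias, K3117 and K3174. Total counts for K3117 were 32136251 in NT, 30913389 in Low and 23132184 in High, and for K3174 they were 22908445, 33265848 and 30304101. Between 99.9218% and 99.9461% of each library fell on the 15812 genes that were tested. With 2 libraries per group, errors below are the SE of the fitted log2 fold change or the SD over the 2 leukemias, and levels are in TMM-normalised CPM.

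Dot1l itself was examined first because its level defines the labels. The gene (ENSMUSG00000061589.14, GRCm38 chromosome 10, 80755206 to 80795461, plus strand, protein coding) was counted at 142.9 ± 21.4 CPM in NT, 167.9 ± 22.4 CPM in Low and 143.1 ± 9.52 CPM in High (SD, n = 2). Its log2 fold change for High over NT was -0.00 ± 0.15 (SE), with a 95% interval for the fold of 0.792 to 1.26 (adjusted p = 1.00). Low over NT gave 0.23 ± 0.14 (adjusted p = 0.62) and High over Low -0.23 ± 0.14 (adjusted p = 0.54). In K3117 the level was 127.8 CPM in NT, 183.7 in Low and 149.8 in High, and in K3174 it was 158.0, 152.0 and 136.4 CPM. Without the K3174 NT library, Low over NT passed the threshold at 0.49 (adjusted p = 0.013), and so did the mean of Low and High over NT at 0.38 (adjusted p = 0.026). The Dot1l counts therefore did not separate the groups in the order of their labels, and the groups are called by their labels throughout. The labels do not state the species or the untranslated regions of the introduced DOT1L, so the mouse gene's count may not include it.

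Neutrophil granule genes were the leading rise in the libraries labelled High compared with NT, and KMT2A fusion targets fell. Ngp, a granule protein of neutrophil precursors (chromosome 9, 110419747 to 110423012, plus strand), went from 8.34 ± 10.3 CPM in NT to 1007 ± 852 CPM in High, 179-fold (log2 7.49 ± 0.40, adjusted p = 6.6e-07). S100a9 and S100a8, which form calprotectin, rose 123-fold (6.94 ± 0.38) and 76.9-fold (6.26 ± 0.38). Flt3, the receptor tyrosine kinase of early progenitors (chromosome 5, 147330741 to 147400489, minus strand), went from 30.3 ± 4.44 to 0.524 ± 0.265 CPM, 59.5-fold lower (-5.89 ± 0.28, adjusted p = 5.5e-07). At an adjusted p of 0.05, 2741 of 15812 genes passed, 1583 higher and 1158 lower, of which 744 and 699 differed by at least 2-fold. Of the 2741 genes, 2739 moved in the same direction in both leukemias, which a test with the leukemia as a block favours. The share with the same sign over all 15812 genes was 65.7%. The plot of both leukemias shows Ngp, S100a9 and Flt3 at the ends of a common diagonal and Dot1l near its centre.

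**Figure D1:**
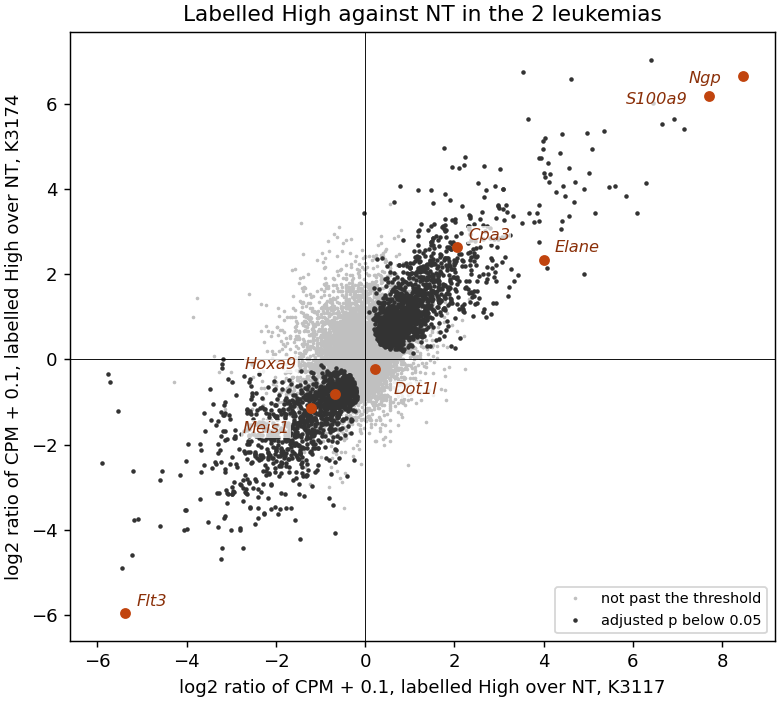
Log2 ratio of CPM + 0.1 between the library labelled High and the NT library, K3117 on the horizontal and K3174 on the vertical axis, for the 15812 genes tested. Dark points are the 2741 genes past an adjusted p of 0.05, grey points the rest, and 8 named genes are in orange. Ngp and S100a9 lie at the upper right and Flt3 at the lower left, while Dot1l is above 0 in K3117 and below 0 in K3174.

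Of 23 measured late neutrophil genes, 22 rose in the libraries labelled High and none fell, with a median log2 fold change of 4.40 (camera adjusted p = 7.2e-28; adjusted p = 0.31 with an estimated correlation). Ltf, the secondary granule protein lactoferrin, rose by 7.26 ± 0.45, Camp, the cathelicidin, by 6.19 ± 0.31, Lcn2, lipocalin, by 5.21 ± 0.22, and Itgb2l, an integrin chain, by 6.51 ± 0.34. Mmp8, a collagenase of mature neutrophils, had a log2 fold change of 0.01 and was the member that did not pass. Retnlg, also on the list, had too few counts to test. In NT, Low and High it had 0, 1 and 0 counts in K3117 and 0, 0 and 4 in K3174. The median was 4.04 in K3117 and 4.53 in K3174. Outside the list, Lrg1 rose by 5.57 ± 0.28. Ankrd22 had no count in either NT library and 53 and 284 counts in the libraries labelled High, at least 53.8-fold higher against a floor of 3 counts per library. Stfa2 (6.29 ± 0.40) and Stfa2l1 (5.45 ± 0.48) belong to a family of near-identical stefin genes, so their separate values are uncertain. Adjusted over the list alone, the count of late neutrophil genes was also 22.

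Primary granule genes rose in 9 of 12 measured members (median 1.62, camera adjusted p = 1.5e-09; adjusted p = 0.31 with an estimated correlation), and 9 rose and 1 fell when adjusted over the list alone. Elane, neutrophil elastase, went from 146.0 ± 122 to 1069 ± 164 CPM (3.15 ± 0.30, adjusted p = 2.8e-05), and Prtn3, proteinase, from 425.3 ± 247 to 1317 ± 220 CPM (1.75 ± 0.19). Prss57 rose by 2.77 ± 0.15 and Gfi1, a transcription factor of granulocyte commitment, by 2.04 ± 0.12. Mast cell and basophil genes rose in 9 of 11 members (median 1.68, camera adjusted p = 4.1e-10; adjusted p = 0.31 with an estimated correlation). Hdc, histidine decarboxylase, rose by 3.52 ± 0.18, Cpa3, the mast cell carboxypeptidase, by 2.39 ± 0.16, and Il1rl1, the interleukin 33 receptor, by 2.63 ± 0.23. Among 24 monocyte and macrophage genes, 12 rose and 3 fell (median 0.72, camera adjusted p = 0.00067; adjusted p = 0.40 with an estimated correlation). Lyz2, lysozyme, rose by 2.09 ± 0.24, and Csf1r, the receptor of macrophage colony-stimulating factor, by 1.40 ± 0.12. Falls were seen for Ccr2 (-1.21 ± 0.16), Irf8 (-1.09 ± 0.20) and Cx3cr1 (-0.70 ± 0.15), which were named after their values were seen. In the mast cell list 9 genes rose, and in the monocyte list 13 rose and 4 fell, adjusted over the list alone.

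**Figure D2:**
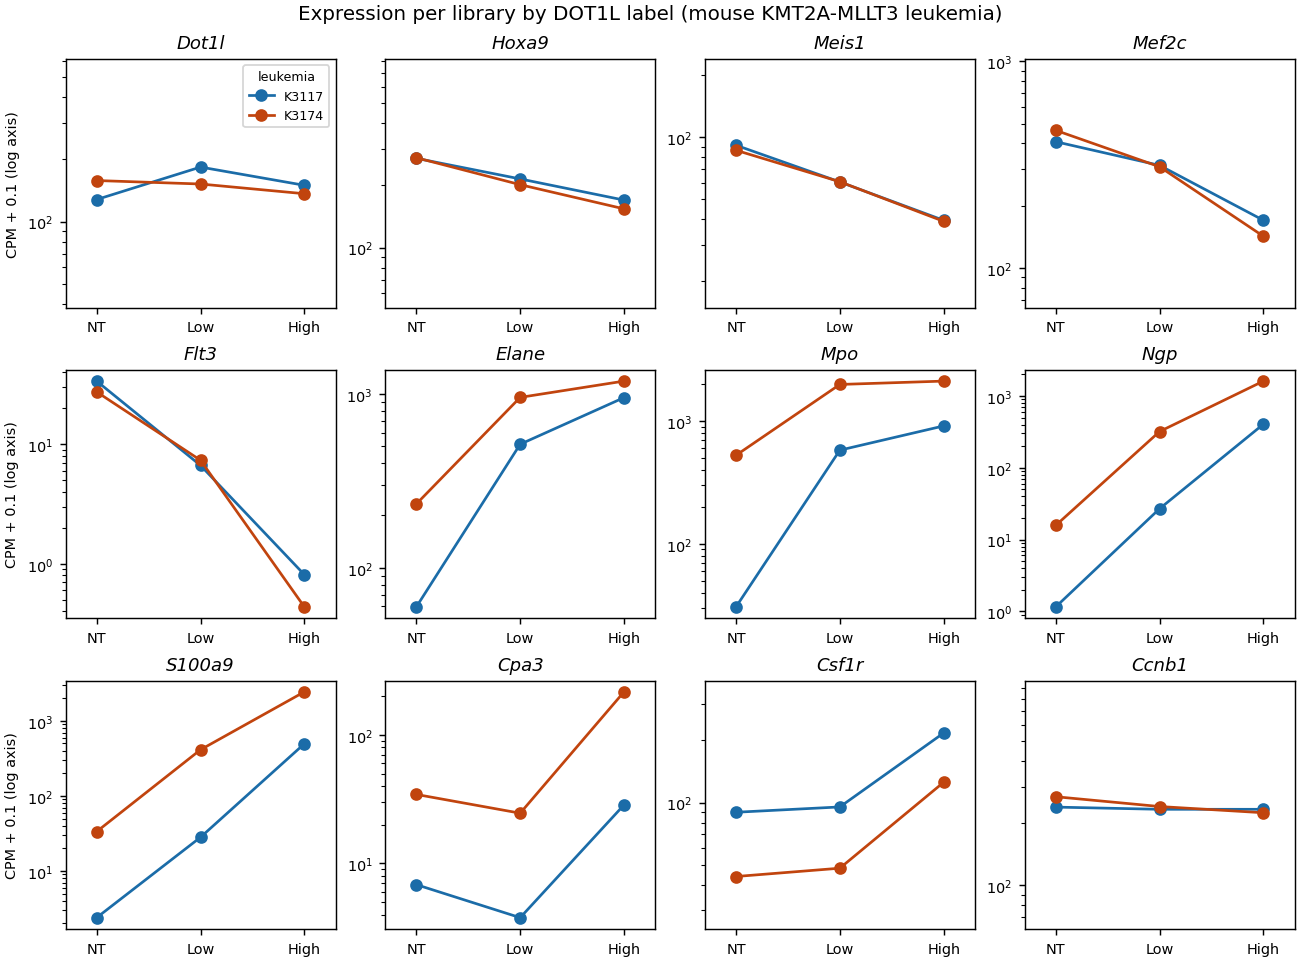
Normalised CPM + 0.1 on log axes of 12 genes in each of the 6 libraries, with lines joining the libraries of K3117 (blue) and K3174 (orange). Hoxa9, Meis1, Mef2c and Flt3 are lower in the libraries labelled High than in NT in both leukemias, Elane, Mpo, Ngp, S100a9, Cpa3 and Csf1r are higher, and Dot1l shows no common order.

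KMT2A fusion targets fell in 17 of 25 measured members of the libraries labelled High, and 1, Cpeb2, rose (median -0.75, camera adjusted p = 9.8e-12; adjusted p = 0.31 with an estimated correlation). Adjusted over the list alone, 18 fell and 1 rose. Hoxa9 (chromosome 6, 52223100 to 52231089, minus strand), a homeobox gene central to these leukemias, went from 271.5 ± 1.30 to 161.8 ± 11.2 CPM (-0.75 ± 0.11, adjusted p = 0.00076). Meis1, its cofactor (chromosome 11, 18879817 to 19018985, minus strand), went from 88.7 ± 3.53 to 39.2 ± 0.320 CPM (-1.18 ± 0.12, adjusted p = 4.7e-05). Hoxa5 fell by 1.81 ± 0.16 on the log2 scale, Hoxa6 by 1.53 ± 0.20, the transcription factor Mef2c by 1.49 ± 0.13, the survival gene Bcl2 by 1.45 ± 0.13, Mecom by 1.30 ± 0.16, Eya1 by 1.18 ± 0.12 and Pbx3 by 0.75 ± 0.12. Myb (0.25 ± 0.13) did not pass. Of 20 genes for DOT1L partners and elongation factors, 5 rose, including Aff1 (0.87 ± 0.12) and Mllt3 (0.72 ± 0.15), and Mllt6 fell (-1.03 ± 0.22), while the list as a whole did not pass (camera adjusted p = 0.095). Mouse Mllt3 counts can also hold reads of the fusion transcript if its cDNA is of mouse origin, which the labels do not state.

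Other genes with large falls in the libraries labelled High were Ddx4, a germ cell helicase (-5.93 ± 0.39), Pacsin1 (-5.85 ± 0.41), Alpi (-5.02 ± 0.35), Tpm2 (-4.64 ± 0.50), Klhl30 (-4.32 ± 0.39), Nes (-4.02 ± 0.39) and Gcnt4 (-4.01 ± 0.26). The noncoding RNAs Rian (-4.15 ± 0.31) and Meg3 (-4.01 ± 0.47) also fell. Dendritic cell and antigen presentation genes fell in 6 of 12 members (median -1.26, camera adjusted p = 5.8e-07; adjusted p = 0.34 with an estimated correlation), among them Flt3, which is on both lists, Itgax (-2.55 ± 0.27), Tcf4 (-1.27 ± 0.11) and H2-Ab1 (-1.32 ± 0.20). Of 23 interferon response genes, 7 fell, including Gbp3 (-1.17 ± 0.14) and Oas3 (-2.60 ± 0.36), and Cxcl10 rose by 1.08 ± 0.24 (camera adjusted p = 0.0033; adjusted p = 0.40 with an estimated correlation). That list no longer passed with genes kept at a CPM of at least 5 (median -0.05, adjusted p = 0.43), without the K3117 NT library (adjusted p = 0.054) or without the K3117 High library (adjusted p = 0.069). Of 4 T and NK cell genes, Lck (-1.22 ± 0.27) and Cd28 (-1.03 ± 0.22) fell (camera adjusted p = 0.0064; adjusted p = 0.46 with an estimated correlation), and Cd28 missed the threshold without the K3174 High library (adjusted p = 0.11). Ighm (-1.91 ± 0.17) and Rag2 (-2.19 ± 0.36) fell among 9 B cell genes, a list that did not pass (camera adjusted p = 0.095). In these lists 7 dendritic cell, 7 interferon, 4 T and NK cell and 3 B cell genes fell and 2 interferon genes rose when adjusted over the list alone.

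Inflammatory NF-kB genes rose in 10 of 21 members and Traf1 fell (median 0.54, camera adjusted p = 0.0022; adjusted p = 0.46 with an estimated correlation). The chemokine Cxcl2 rose by 2.58 ± 0.19, the interleukin 1 antagonist Il1rn by 1.49 ± 0.18 and Il1b by 1.40 ± 0.20. Without the K3117 NT library the list had an adjusted p of 0.078. Immediate early genes rose in 8 of 19 members, among them Ier3 (1.14 ± 0.14) and Fos (1.26 ± 0.23) (camera adjusted p = 0.0064; adjusted p = 0.55 with an estimated correlation), with an adjusted p of 0.083 without the K3174 High library. Of 23 cholesterol synthesis genes 7 rose, including Fdps (1.11 ± 0.19) and Nsdhl (0.90 ± 0.13) (camera adjusted p = 0.00068; adjusted p = 0.64 with an estimated correlation). The cholesterol median was 0.55 in K3117 and 0.02 in K3174, and the list did not pass without the K3117 NT library (adjusted p = 0.17) or the K3117 High library (adjusted p = 0.36). Pf4 (2.57 ± 0.54) and Gp5 (1.49 ± 0.36) rose among 10 megakaryocyte genes at 1.16 and 2.92 CPM in High (camera adjusted p = 0.035; adjusted p = 0.64 with an estimated correlation). That list did not pass without the NT library of K3117 (adjusted p = 0.13) or of K3174 (adjusted p = 0.074), or without the K3174 High library (adjusted p = 0.32). Adjusted over the list alone, 11 NF-kB genes rose and 2 fell, 9 immediate early genes rose and 3 fell, and 9 cholesterol and 4 megakaryocyte genes rose.

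Cell cycle lists showed little movement in the libraries labelled High. None of 25 G2 and M phase genes passed by edgeR (median -0.01, from -0.23 to 0.25, camera adjusted p = 0.80), and 1 of 27 S phase genes, Cdca7, fell (-0.38 ± 0.11). The S phase list had a camera adjusted p of 0.082. It passed downward without the leukemia block (adjusted p = 0.043) or with a CPM of at least 5 (adjusted p = 0.047). MYC and ribosome biogenesis genes had a median of -0.24 with Cad as the member that fell (-0.60 ± 0.17), and cytoplasmic ribosomal proteins had a median of -0.10 with none of 35 past the threshold. Mitochondrially encoded genes had a median of 0.29 with mt-Cytb past the threshold (0.44 ± 0.14). These 3 lists passed camera (adjusted p = 0.0016, 0.016 and 0.0064; each adjusted p = 0.64 with an estimated correlation). They no longer passed without the K3174 NT library (adjusted p = 0.36, 0.21 and 0.52) or without the K3174 High library (adjusted p = 0.40, 0.37 and 0.25), where Cad (adjusted p = 0.21) and mt-Cytb (adjusted p = 0.41) did not pass either. None of the S phase, MYC, ribosomal or mitochondrial genes passed by edgeR when adjusted over the list alone. Of 25 p53 targets, 4 rose, including Perp (2.39 ± 0.17) and Fas (1.89 ± 0.20), and 2 fell (camera adjusted p = 0.44). Lists of stem and progenitor genes (adjusted p = 0.095), erythroid genes (0.15), stromal and endothelial genes (0.45), Cdkn inhibitors and apoptosis genes (0.68), unfolded protein and integrated stress response genes (0.45), heat shock genes (0.16), hypoxia and glycolysis genes (0.23), replication-dependent histone genes (0.93) and long neuronal or muscle genes (0.17) did not pass. Among stem and progenitor genes, Hlf (-2.77 ± 0.25) and Cd34 (-0.92 ± 0.18) were lower and Kit (0.68 ± 0.11) higher. Of its 19 measured members, that list had 7 lower and 2 higher past the threshold, also when adjusted over the list alone. It passed downward with a CPM of at least 5 (adjusted p = 0.036) and without the K3117 NT (0.036), K3117 Low (0.046), K3174 Low (0.046) or K3174 High library (0.030). Heat shock genes passed downward without the K3117 NT (0.011) or K3117 High library (0.0071), hypoxia and glycolysis genes (0.043) and S phase genes (0.041) without the K3117 NT library, and B cell genes without the K3174 High library (0.034).

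The test for High against NT was edgeR's quasi-likelihood test with the leukemia as a block. Without that replicate block 493 genes passed, all among the 2741, with 6 of the 23 late neutrophil genes and 10 of the 25 fusion targets, and all 15 lists that passed camera still passed. Many named genes did not pass without the block, among them Ngp (adjusted p = 0.098), S100a9 (0.13), Ltf (0.13), Camp (0.13), Elane (0.074), Cpa3 (0.33) and Csf1r (0.19), while Hoxa9, Meis1, Mef2c and Flt3 still passed. Over all contrasts, 185 of the 210 named gene results past the threshold fell below it without the block. Without the K3117 NT library 4394 genes passed. Of the 2741 calls 57.8% were higher, against 49.1% of 2748 with library sizes alone and 43.9% of 2953 with upper quartile factors, which moved the median log2 fold change of all genes from -0.01 to -0.11.

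**Figure D3:**
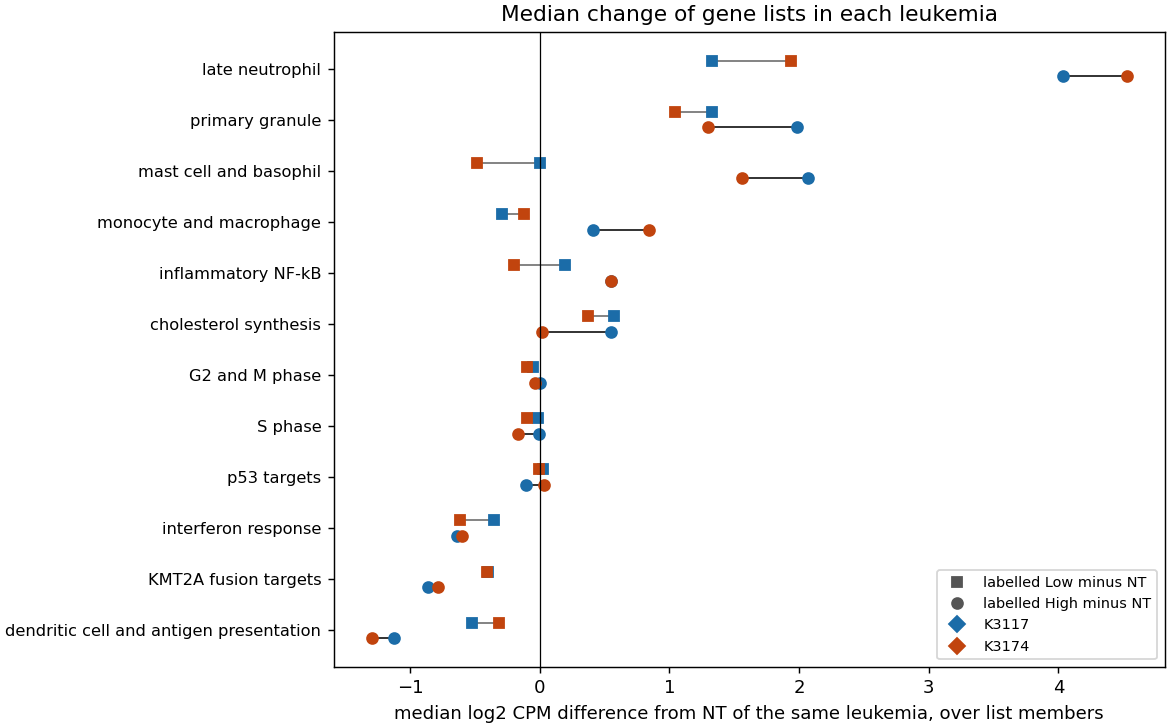
Median log2 CPM difference from the NT library of the same leukemia over the members of 12 gene lists, for libraries labelled Low (squares) and High (circles) in K3117 (blue) and K3174 (orange), with a line joining the leukemias. Late neutrophil genes lie at 1.33 and 1.94 for Low and at 4.04 and 4.53 for High, while G2 and M phase genes lie near 0.

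In the libraries labelled Low, the same neutrophil lists were higher than in NT by smaller amounts. Ngp rose 20.1-fold to 173.0 ± 207 CPM (4.33 ± 0.36, adjusted p = 0.00018), S100a9 rose 11.8-fold (3.56 ± 0.33), Camp 10.1-fold (3.33 ± 0.30), Ltf by 3.50 ± 0.46, Itgb2l by 3.67 ± 0.36 and Lrg1 by 3.51 ± 0.29. Late neutrophil genes rose in 16 of 23 members (median 1.78, camera adjusted p = 1.2e-25; adjusted p = 0.30 with an estimated correlation), or 17 with 1 lower when adjusted over the list alone. Primary granule genes rose in 9 of 12 members (median 1.12, camera adjusted p = 4.6e-19; adjusted p = 0.29 with an estimated correlation), with Elane 5.66-fold (adjusted p = 0.00084), Prtn3 2.47-fold (1.31 ± 0.18) and Gfi1 2.73-fold (1.45 ± 0.12) higher. Cholesterol synthesis genes rose in 4 of 23 members, and in 14 when adjusted over the list alone (median 0.40, camera adjusted p = 4.2e-15; adjusted p = 0.45 with an estimated correlation), with Nsdhl (0.84 ± 0.13), Mvd (0.82 ± 0.16), Sqle (0.64 ± 0.13) and Fdft1 (0.61 ± 0.13) past the threshold. Without the K3174 Low library none of the 4 passed (adjusted p = 0.068, 0.060, 0.13 and 0.32), and without the K3117 Low library Mvd (0.056), Sqle (0.12) and Fdft1 (0.11) did not.

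KMT2A fusion targets fell in 5 of 25 members of the libraries labelled Low, and 14 fell and 1 rose when adjusted over the list alone (median -0.42, camera adjusted p = 2.1e-09; adjusted p = 0.29 with an estimated correlation). The 5 were Flt3 (-2.13 ± 0.21), Hoxa5 (adjusted p = 0.0043), Hoxa6 (-0.85 ± 0.19), Meis1 (-0.55 ± 0.12) and Jmjd1c (-0.55 ± 0.13). Hoxa9 had a log2 fold change of -0.38 ± 0.11 (adjusted p = 0.11) and Mef2c of -0.49 ± 0.13 (adjusted p = 0.072). Without the K3174 Low library 1 target fell, and without the K3117 Low library 2 did. Meis1 did not pass in either case (adjusted p = 0.32 and 0.31), nor did Hoxa6 (0.52 and 0.17) or Jmjd1c (0.37 and 0.33), nor Hoxa5 without the K3174 Low library (adjusted p = 0.13). Dendritic cell and antigen presentation genes fell in 3 of 12 members, Flt3, Itgax (-1.85 ± 0.25) and Tcf4 (-0.50 ± 0.11) (camera adjusted p = 5.3e-07; adjusted p = 0.30 with an estimated correlation), and in 6 when adjusted over the list alone. Tcf4 did not pass without the K3174 Low library (adjusted p = 0.34). Other large falls were Ddx4 (-3.29 ± 0.29), Fn1, fibronectin (-2.38 ± 0.32), Dlk1 (-2.33 ± 0.24), Abcb4 (-2.32 ± 0.25) and the globin Hbb-bt (-2.62 ± 0.42), whose reads can be shared with its paralog.

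Mast cell and basophil genes did not rise as a list in the libraries labelled Low (median -0.28, camera adjusted p = 0.18), with Hdc higher (1.86 ± 0.17) and Prss34 lower (-2.05 ± 0.48). Of 24 monocyte and macrophage genes, Ly6c2 rose (0.56 ± 0.12) and Ccr2 (-1.56 ± 0.16) and Ctss (-0.55 ± 0.13) fell (camera adjusted p = 0.096). The mast cell list passed downward without the K3117 Low library (adjusted p = 0.019), and the monocyte list without the K3174 NT (0.015), K3174 Low (0.029), K3174 High (0.040) or K3117 High library (0.0497). Other lists passed camera downward with few members past the threshold, namely stem and progenitor genes (Hlf -1.49 ± 0.22 and Gfi1b -1.51 ± 0.31, with Kit higher at 0.73 ± 0.11; adjusted p = 0.022), T and NK cell genes (Il7r -2.19 ± 0.35; 0.048), B cell genes (Ighm -0.83 ± 0.16; 0.013), interferon response genes (Oasl2 -1.93 ± 0.46; 0.00032) and cytoplasmic ribosomal proteins (no member; 0.00031). Mitochondrially encoded genes passed upward with no member past the threshold (median 0.19, adjusted p = 0.0024). With an estimated correlation the adjusted p of these 6 lists lay between 0.45 and 0.60. Adjusted over the list alone, 4 stem and progenitor, 1 T and NK cell, 2 B cell, 7 interferon, 4 mast cell and 3 monocyte genes fell, and 2, 0, 0, 1, 1 and 1 rose. Without the K3174 Low library Gfi1b (adjusted p = 0.22), Ighm (0.18) and Oasl2 (0.57) did not pass, nor Il7r without the K3117 Low library (0.087). Without the replicate block, the stem and progenitor list (adjusted p = 0.079) and the T and NK cell list (adjusted p = 0.11) did not pass. Leaving out 1 library ended the call of T and NK cell genes (without K3174 NT, adjusted p = 0.26), B cell genes (without K3117 NT, 0.13), stem and progenitor genes (without K3174 NT, 0.14), interferon genes (without K3117 NT, 0.059; also with a CPM of at least 5, median 0.0060, 0.48), ribosomal proteins (without K3174 NT, 0.094) and mitochondrial genes (without K3174 Low, 0.36).

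In all, 528 genes passed for Low against NT, 324 higher and 204 lower, and all 528 had the same direction in both leukemias. The test with the block favours genes that agree, so this is no separate support. Over all 15812 genes tested, 52.5% of the Low minus NT differences had the same sign in both leukemias. With robust dispersion Ngp (adjusted p = 0.11), S100a9 (0.13), Elane (0.17) and Ltf (0.22) did not pass. Without the replicate block edgeR called 0 genes (950 at an unadjusted p under 0.05), limma-voom 0 and DESeq2 152. The count was 144 without the K3174 Low library, and 1483, 885, 958 and 951 without the K3117 NT, K3174 NT, K3117 High and K3174 High libraries. The share of higher calls was 61.4%, against 45.6% of 881 with only the compared groups, 46.5% of 958 without the K3117 High library and 45.3% of 951 without the K3174 High library.

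Between the sorted populations, the libraries labelled High exceeded those labelled Low in neutrophil, mast cell and monocyte genes. Ear6, an eosinophil-associated ribonuclease of a multigene family, rose 17.4-fold (4.12 ± 0.42), Akr1c18 16.4-fold (4.03 ± 0.30), Ltf 13.5-fold (3.76 ± 0.34), Tph1, which starts serotonin synthesis, 13.1-fold (3.71 ± 0.34), and Chil3 10.8-fold (3.43 ± 0.42). With robust dispersion Ltf (adjusted p = 0.086) and Chil3 (adjusted p = 0.24) did not pass. Late neutrophil genes rose in 21 of 23 members (median 2.56, camera adjusted p = 3.5e-39; adjusted p = 0.20 with an estimated correlation), and in all 23 when adjusted over the list alone, with Lcn2 up by 2.82 ± 0.18, Cd177 by 2.88 ± 0.22 and Camp by 2.86 ± 0.24. All 11 mast cell and basophil genes rose (median 2.06, camera adjusted p = 6.3e-21; adjusted p = 0.20 with an estimated correlation), Cpa3 by 3.05 ± 0.16, Il1rl1 by 2.97 ± 0.23 and Ms4a2, a chain of the high-affinity IgE receptor, by 2.06 ± 0.19. Of 24 monocyte and macrophage genes, 12 rose and none fell (median 1.02, camera adjusted p = 6.8e-11; adjusted p = 0.20 with an estimated correlation), with Lyz2 at 2.00 ± 0.24, Adgre1, the F4/80 antigen, at 1.55 ± 0.13 and Csf1r at 1.29 ± 0.12. Of the monocyte genes 15 rose and 4 fell when adjusted over the list alone. Without the K3117 Low library 6 monocyte genes rose over all genes, and without the K3174 Low library 7 mast cell genes rose.

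KMT2A fusion targets were lower again in the libraries labelled High than in those labelled Low, in 7 of 25 members, or 15 when adjusted over the list alone (median -0.42, camera adjusted p = 1.8e-11; adjusted p = 0.20 with an estimated correlation). The 7 were Flt3 (-3.77 ± 0.29), Bcl2 (-1.04 ± 0.13), Mef2c (adjusted p = 0.0010), Mecom (-0.94 ± 0.16), Hoxa5 (-0.81 ± 0.16), Eya1 (-0.73 ± 0.12) and Meis1 (-0.63 ± 0.12), while Hoxa9 had -0.37 ± 0.11 (adjusted p = 0.10). Without the K3174 Low library 4 fell. Meis1 did not pass when either Low or either High library was left out (adjusted p between 0.072 and 0.12), nor Hoxa5 without the K3117 Low library (adjusted p = 0.28), nor Mecom (0.052) and Eya1 (0.065) without the K3174 Low library. Gcnt4 (-2.66 ± 0.27), Mrvi1 (-2.45 ± 0.31), Rian (-2.38 ± 0.32), Pcp4l1 (-2.25 ± 0.28) and Afm (-2.18 ± 0.31) were the other leading falls, of which Rian missed the threshold without the K3174 High library (adjusted p = 0.11) and Afm without the K3117 High library (adjusted p = 0.090). Dendritic cell and antigen presentation genes fell in 3 of 12 members (Flt3, Siglech and Tcf4, of which Siglech did not pass without the K3117 Low library, adjusted p = 0.14; camera adjusted p = 2.5e-05, or 0.28 with an estimated correlation), and in 6 when adjusted over the list alone. Erythroid genes rose in 4 of 10 members and megakaryocyte genes in 4 of 10 (each camera adjusted p = 4.0e-05; adjusted p = 0.25 and 0.61 with an estimated correlation). There were 7 erythroid and 6 megakaryocyte genes that rose when adjusted over the list alone. Without the K3117 Low library none of Car2 (adjusted p = 0.19), Hbb-bs (0.23), Car1 (0.19) and Hba-a1 (0.27) passed, and without the K3174 Low library none of Gp5 (0.071), Itga2b (0.072), Vwf (0.13) and Pf4 (0.22) did. With genes kept at a CPM of at least 5 neither list passed, with medians of -0.022 (adjusted p = 0.55) and 1.36 (adjusted p = 0.072).

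Among primary granule genes, Prss57 (0.96 ± 0.14) and Gfi1 (0.59 ± 0.12) were past the threshold between the libraries labelled High and Low, and 8 of 12 rose and 1 fell when adjusted over the list alone (median 0.45, camera adjusted p = 0.0055; adjusted p = 0.61 with an estimated correlation). Gfi1 did not pass without the K3117 Low library (adjusted p = 0.21), nor Prss57 (adjusted p = 0.054). The list did not pass without the replicate block (adjusted p = 0.28) or without the K3117 High library (adjusted p = 0.69). Inflammatory NF-kB genes rose in 4 of 21 members, Il6, Il1rn, Il1b and Cxcl2 (camera adjusted p = 0.00041; adjusted p = 0.64 with an estimated correlation), and immediate early genes in 3 of 19, Fos, Btg2 and Klf6 (0.0026; adjusted p = 0.65 with an estimated correlation). Adjusted over the list alone, 9 NF-kB genes rose and 2 fell, and 8 immediate early genes rose. Il6 did not pass without the K3174 High library (adjusted p = 0.37). Klf6 did not pass without either Low library (0.14 and 0.24) or either High library (0.067 and 0.25) of K3117 and K3174, nor Btg2 without the K3117 Low (0.41), K3174 Low (0.058) or K3174 High library (0.40). Immediate early genes did not pass without the Low (adjusted p = 0.28) or High (adjusted p = 0.20) library of K3174. MYC and ribosome biogenesis genes (median -0.17, camera adjusted p = 3.5e-05; adjusted p = 0.69 with an estimated correlation) and cholesterol synthesis genes (median -0.07, 0.039; adjusted p = 0.78 with an estimated correlation) passed downward. Both calls ended without the K3174 High library (adjusted p = 0.45 and 0.47), where the cholesterol median was 0.09. In all, 866 genes passed, 652 higher and 214 lower, of which 864 had the same direction in both leukemias. That agreement is favoured by the block, and the share with the same sign over all 15812 genes was 63.1%. Without the replicate block edgeR called 0 genes (1238 at an unadjusted p under 0.05), limma-voom 0 and DESeq2 291. The count was 335 and 489 without the K3117 and K3174 Low libraries, and 1982 and 1934 without the K3117 and K3174 NT libraries.

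Averaging the libraries labelled Low and High against NT gave 1979 genes, 1056 higher and 923 lower, with Ngp (5.91 ± 0.37), S100a9 (5.25 ± 0.34) and Ltf (5.38 ± 0.43) leading the rises and Ddx4 (-4.61 ± 0.26), Pacsin1 (-4.02 ± 0.28) and Flt3 (-4.01 ± 0.19) the falls. Late neutrophil genes rose in 19 of 23 members and KMT2A fusion targets fell in 16 of 25, or 17 when adjusted over the list alone (camera adjusted p = 3.3e-26 and 1.0e-11; each adjusted p = 0.26 with an estimated correlation). Hoxa9 (-0.57 ± 0.10), Meis1 (-0.86 ± 0.10) and Mef2c (-0.99 ± 0.11) were among the falls. Without the replicate block 89 genes passed, and without the K3117 NT library 3302 did. Ngp (adjusted p = 0.18), S100a9 (0.24), Ltf (0.25), Ddx4 (0.0504), Pacsin1 (0.077) and Hoxa9 (0.053) were among those that did not pass without the block. The share of higher calls was 53.4%, against 48.2% of 1947 calls with library sizes alone, 43.4% of 2085 with upper quartile factors and 47.4% of 2015 without the K3174 High library. In this average 15 lists passed camera, of which stem and progenitor genes (adjusted p = 0.090), B cell genes (0.090) and immediate early genes (0.087) did not pass without the block. With an estimated correlation no list passed (smallest adjusted p = 0.26).

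Of the 324 genes higher in Low, 322 were also called higher in High, and of the 204 lower in Low, 173 were also called lower, while 3 were called in opposite directions. Independent lists of these sizes would share 32.4 and 14.9 genes. Counts simulated for all libraries with no effect of the labels, with NT common to both comparisons, shared 0.30 called genes on average. Few genes are called at all without an effect, so that value gives no expected overlap for lists of these sizes. Across the 15812 genes, which are not independent replicates, the fold changes of Low and High over NT had a Pearson correlation of 0.748, against 0.507 in the simulation, and a covariance of 0.346 against 0.0567. The simulation already held the noise that the shared NT libraries add at the fitted dispersions. The NT libraries were too few to split, so a deviation of NT beyond that spread may still be part of the excess. Comparisons that share no library gave lower values, though they set single libraries against each other and not fold changes fitted to all libraries. The High minus NT differences of K3117 and K3174 had a Pearson correlation of 0.648 (Spearman 0.487). For the Low minus NT differences it was 0.404 (Spearman 0.212). The High difference of K3117 correlated with the Low difference of K3174 at 0.503 (Spearman 0.368), and the converse pair at 0.364 (Spearman 0.213).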

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

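The tests in this part were all chosen after the results were seen. The 3 patterns weighed are the late neutrophil rise, the Dot1l counts and the fall of KMT2A fusion targets, all for High against NT.

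Depth could not produce the late neutrophil rise, because the High to NT ratio of total counts was 0.720 in K3117 and 1.32 in K3174 while the list's median log2 difference was at least 4.04 in each. A wrong scaling factor would shift all genes alike, but the list's median exceeded that of all other tested genes by 4.41 (95% bounds over resampled members 3.21 to 5.22). Mature neutrophils mixed in, a sort gate, nonleukemic granulocyte precursors and a direct effect of DOT1L on maturation stay open, and none of them was settled.

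The Dot1l counts might lie level because the High and NT labels were exchanged in 1 leukemia, but the High minus NT differences of the leukemias correlated at 0.648. Such an exchange would give a negative value. This correlation cannot exclude an exchange of Low with High or of Low with NT in 1 leukemia. Reads of an introduced DOT1L of another species or without its untranslated regions may not be counted on the mouse gene, which the upper bound of 1.26 for the fold cannot test. Reads over the construct or a protein measurement would tell.

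Scaling could not explain the fall of KMT2A fusion targets on its own, because their median lay below that of all other tested genes, with a difference of -0.73 (95% bounds over resampled members -1.17 to -0.43). Dilution by cells without the fusion may contribute and stays open, since which members such cells express was not measured. Whether lower fusion target expression follows from maturation or precedes it was not tested.

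Some values had opposite signs in the 2 leukemias, and the difference was not tested. The median of mitochondrially encoded genes for Low against NT was -0.033 in K3117 and 0.44 in K3174, that of cholesterol synthesis genes for High against Low 0.026 and -0.24, and that of MYC and ribosome biogenesis genes for the mean against NT 0.018 and -0.32. The Dot1l log2 difference was 0.23 and -0.21 for High against NT, 0.52 and -0.06 for Low against NT and 0.38 and -0.13 for the mean against NT.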

How the results depend on the processing

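Most choices below were fixed before the values were seen, and the test of the steps from NT to Low and Low to High was added afterwards. The cause was not tested for any difference unless the construction shows it.

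Dropping the replicate block changed the counts most, to 493 for High against NT, 0 for Low against NT, 0 for High against Low and 89 for the mean against NT. It moves the difference between the leukemias into the error, which by construction widens it. With no filter on low counts Low against NT gave 1071 genes and High against Low 1425. With a CPM of at least 5, High against Low gave 568 and K3174 against K3117 gave 932. Using only the compared groups gave 881 for Low against NT and 1864 for High against Low. A threshold of 0.1 gave 813 for Low against NT. Asking also for an absolute log2 fold change of at least 1 gave 1443, 284, 508, 912 and 780 genes for High against NT, Low against NT, High against Low, the mean against NT and K3174 against K3117, fewer by construction. With an estimated correlation camera passed 0, 0, 0 and 0 lists in the first 4 of these.

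Leaving out 1 library gave from 1927 to 4394 genes for High against NT, from 144 to 1483 for Low against NT, from 335 to 1982 for High against Low, from 1417 to 3302 for the mean against NT and from 829 to 2642 for K3174 against K3117.

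The log2 fold change of Dot1l for High against NT was 0.00030 with RLE factors, 0.011 with limma-voom, 0.0021 without the block and 0.0097 with only the compared groups, all near 0. Leaving out 1 library gave from -0.25 to 0.27 for High against NT, from -0.016 to 0.49 for Low against NT and from -0.13 to 0.38 for the mean against NT. Among the list medians that changed sign when 1 library was left out, the range was from -0.21 to 0.14 for MYC and ribosome biogenesis genes and from -0.029 to 0.48 for mitochondrially encoded genes (Low against NT), from -0.31 to 0.021 for MYC and ribosome biogenesis genes (mean against NT), and from -0.28 to 0.088 for cholesterol synthesis genes (High against Low). For Low against NT, the MYC list passed downward without the K3117 NT library (adjusted p = 0.00061) and upward without the K3174 NT library (adjusted p = 0.0021), so the NT library kept decided the direction. Inflammatory NF-kB genes, at -0.022 with all libraries, passed upward without the K3174 NT library (0.16, adjusted p = 0.012) and without the K3174 Low library (0.12, adjusted p = 0.032). With a CPM of at least 5 the median of interferon response genes (Low against NT) went from -0.39 to 0.0060 and that of erythroid genes (High against Low) from 1.34 to -0.022, over fewer members by construction.

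The correlation between the leukemias rose with a CPM of at least 5, a filter that also changes which genes enter. It was 0.809 for High minus NT in both, 0.510 for Low minus NT in both, 0.481 for Low of K3117 with High of K3174, 0.699 for the converse and 0.738 for High minus Low. A prior count of 0.5 gave 0.625 for High minus NT, 0.473 for High of K3117 with Low of K3174 and 0.485 for High minus Low, and a prior count of 5 gave 0.671, 0.532 and 0.559.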

Other observations

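The contrast of K3174 with K3117 was planned, and every other observation and test in this part was chosen after the results were seen.

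Mast cell, monocyte and other lineage genes may respond mainly in a second step, after the level of the libraries labelled Low. The spacing of DOT1L levels between the labels was not measured, so a larger step in expression may reflect only a larger step in DOT1L. In Low the list medians lay below NT, at -0.28 (mast cell), -0.23 (monocyte), -0.96 (erythroid) and -0.54 (megakaryocyte), which adds to the later step. None of these lists passed in Low (camera adjusted p between 0.052 and 0.18), and Hdc already rose there. Erythroid genes did not pass for High against NT either (camera adjusted p = 0.15). In a test of whether the step from Low to High differs from that from NT to Low, 56 genes passed, 55 with the larger value from Low to High, among them 6 of 11 mast cell and basophil genes, such as Cpa3 (3.71 ± 0.30), and 5 of 24 monocyte and macrophage genes, while 0 primary granule genes did. Adjusted over the list alone, 10 mast cell, 11 monocyte, 6 of 10 erythroid and 4 of 10 megakaryocyte genes had the larger step from Low to High and 5 of 12 primary granule genes the smaller. The list medians were 2.14 for mast cell, 1.00 for monocyte, 2.98 for erythroid, 1.99 for megakaryocyte and -0.71 for primary granule genes (camera adjusted p = 3.2e-23, 3.0e-16, 1.6e-06, 7.7e-07 and 5.3e-14). With an estimated correlation these were adjusted p = 0.24, 0.24, 0.24, 0.59 and 0.24, so none of these lists passed. By the preset test the pattern was not particular to mast cell and monocyte genes, since erythroid and megakaryocyte genes moved with them. For High against Low, however, neither the erythroid nor the megakaryocyte list passed with genes kept at a CPM of at least 5. Their medians there were -0.022 and 1.36 (camera adjusted p = 0.55 and 0.072). In the test of the steps without the replicate block, edgeR called 0 genes (269 at an unadjusted p under 0.05), limma-voom 0 and DESeq2 11. With genes kept at a CPM of at least 5 the count was 13 with the block. The count was 8 genes without the K3174 Low library, with 1 mast cell gene, and 19 without the K3117 Low library, with 3. It was 263, 439, 288 and 156 without the K3117 NT, K3174 NT, K3117 High and K3174 High libraries. The idea would fail if a graded series of DOT1L levels raised Cpa3 and Gfi1 in parallel.

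Of the imprinted genes of a cluster on chromosome 12, picked by eye and not tested as a list, 4 fell in the libraries labelled High. Dlk1 (109452823 to 109463336, plus strand) had a log2 fold change of -3.88 ± 0.26 (adjusted p = 2.9e-06), Meg3 (109541001 to 109571726, plus strand) -4.01 ± 0.47, Rian -4.15 ± 0.31 and Mirg -5.08 ± 0.87 (adjusted p = 0.0017). Dlk1 fell from 3510 counts in NT to 253 in High in K3117 and from 5400 to 322 in K3174. Dlk1 is expressed from the paternal and the other 3 from the maternal chromosome, and allele use was not measured. Meg3 and Mirg were near the floor in K3117, with 14 and 2 counts in NT and 2 and 0 in High. Of the same cluster Rtl1 had too few counts to test and Dio3 had 0. Without the replicate block Rian (adjusted p = 0.24) and Meg3 (adjusted p = 0.31) did not pass. Meg3 also differed between the leukemias (4.73 ± 0.40), with 14 counts in NT of K3117 and 497 in NT of K3174.

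The 2 leukemias differed from each other across all labels, in 1481 genes, 482 higher and 999 lower in K3174. The replicates of this contrast are the differently labelled libraries of 1 leukemia on each side. Its p-values therefore measure the spread between libraries and not that between leukemias. Late neutrophil genes were higher in K3174 in 17 of 23 members (median 1.65, camera adjusted p = 8.6e-22; adjusted p = 0.28 with an estimated correlation) and monocyte and macrophage genes lower in 13 of 24 (median -0.74, camera adjusted p = 1.6e-09; adjusted p = 0.28 with an estimated correlation). In all, 22 of 29 lists passed. Mast cell genes were higher in 9 of 11 members (median 1.59) and primary granule genes in 8 of 12 (median 0.62), and interferon response genes were lower in 8 of 23 (median -0.79) (camera adjusted p = 1.4e-11, 7.5e-08 and 9.2e-09; each adjusted p = 0.28 with an estimated correlation). Fcnb, a ficolin of granulocyte precursors, was 26.5-fold higher in K3174 (4.73 ± 0.20). Psma8 and Tex14, genes of the germ line, were higher in K3174 (9.65 ± 0.32 and 5.09 ± 0.29), as were Xlr4a (9.84 ± 0.39) and Xlr4b (6.68 ± 0.40), near-identical copies whose reads can be shared. Rnf17, another germ line gene (-7.56 ± 0.39), Nrap (-5.65 ± 0.34), Pi15 (-5.33 ± 0.37), Zfp783 (-4.38 ± 0.25), Eps8l1 (-4.29 ± 0.27) and Colec12 (-4.03 ± 0.23) were lower in K3174. In the NT, Low and High libraries Psma8 had 1, 1 and 0 counts in K3117, Xlr4a 1, 0 and 0 in K3117, and Rnf17 0, 1 and 2 in K3174, so these folds are poorly bounded. The count of genes was 829 and 858 without the K3117 and K3174 Low libraries, and 2642 and 2532 without the K3117 and K3174 NT libraries.

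The grouping by K number was compared with the other groupings of the libraries. Of the 10 ways to split the 6 libraries into 3 and 3, only 1, the real one, gave as many as 1481 genes, and the highest other count was 0. With 10 splits the share cannot fall below 0.05, so this comparison is too small to decide. Every other split also mixed the K numbers on each side, so a difference between the leukemias would widen its error by construction. The low counts of those splits therefore give no separate support.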
